A study of Mus musculus with 6 samples.

How the data were processed

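The series measured total RNA of mouse CD8+ T cells on Illumina bead arrays after labelling with streptavidin-Cy3, in 6 samples: DMSO, epoxomicin and E9, with 2 arrays each. Samples were grouped by their titles. The values used were the authors' deposited intensity table, on a linear scale and rounded to 1 decimal. Its sorted values are identical in every column, so the authors had quantile-normalized it across the arrays. The scanner software and the handling of background are not stated. The lowest values and their mode near 30.7 lie above 0, so background was treated as still present, though the values do not settle this. A second table of non-normalized values was not used here, since its 6 value columns carry running numbers that match no sample label. The plan written before the data were examined had foreseen raw intensities with detection p-values. It allowed normexp correction with an offset of 50 where these were lacking, and this was applied to the quantile-normalized values. Quantile normalization gives every array one set of intensities, so a change in the total amount of RNA cannot be seen, and counts of probes above background are equal by construction.

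Background was estimated from the intensities: the mode was 30.7 and the SD of the values below it 2.32, which put the detection limit at 34.5 (one-sided probability 0.05). Intensities were background-corrected with normexp (offset 50) and log2-transformed; the offset shrinks fold changes of dim genes, whose printed values are therefore smaller than the ratio of their signals. Of 45281 probes, 35784 carried 1 gene symbol, 0 several and 9497 none. Symbols of 31257 probes were matched to RefSeq and 4527 kept the symbol of the array annotation. Probes were kept if above the limit on at least 2 arrays, which left 20349 named probes and, with the probe of highest mean per gene, 13524 genes, of which 4521 had more than 1 kept probe. Where 1 group was not above the limit, the fold of a changed gene is given as a bound against the limit, while genes named whatever their values and the genes counted below for opposite signs carry fitted values.

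Genes were tested with limma (lmFit and eBayes) in 1 model of the 3 groups, with 3 residual and 6.32 prior degrees of freedom, 3 comparisons and Benjamini-Hochberg adjustment within each; a gene rose, fell or changed if its adjusted p was under 0.05. The median SE was 0.0722. The 40 gene lists were fixed in advance, 39 of them with at least 4 measured members, and cover the proteasome, protein and oxidative stress, metabolism, CD8+ T cell states, signalling, the cell cycle and markers of other cell types. Lists were tested with camera at a preset correlation of 0.01 and called at an adjusted p under 0.05. They were tested again with an estimated correlation and with fry. With an estimated correlation camera uses only the 3 residual degrees of freedom, so few lists could pass after adjustment. Failing it does not tell correlation between members from too few arrays, and passing at the preset value leaves correlation unsettled. The genes whose groups did not overlap made up 41.5%, 51.4% and 50.1% of those tested, in the order epoxomicin against DMSO, E9 against DMSO and epoxomicin against E9, where chance gives 33.3%. Shared controls were modelled with 100 simulations of unchanged groups.

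The rule for named genes took, per comparison, the 8 highest and 8 lowest changed genes whose groups did not overlap and that were detected in each group, leaving out names that are only clone or accession labels. It added up to 4 bounds each way, up to 4 changed members of each list, and 21 genes named whatever their values, 1 of which is not reported here; a list with no changed member could name up to 2 with the smallest p. Not every list member is named here.

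The procedure was tested on simulated data with the real means and spreads of 13524 genes. Of 50 genes shifted by 0.25, the comparisons recovered 26%, 16% and 38%, and of those shifted by 0.5, 100%, 96% and 100%; all shifted by 1 or 2 were recovered, with 11, 11 and 17 of 13324 unshifted genes passing. A list shifted by 0.5 was called in each of 3 runs and no other list was. The genes were drawn independently, so these runs cannot show how correlation between members affects list calls. Smaller list shifts were not simulated. Alternatives tried were a block for the replicate number, a fit of the compared groups alone, no background correction, no filter and a stricter filter on dim probes, the mean of all probes of a gene, eBayes with trend and robust settings, a 2-fold threshold and leaving out each array. An offset of 16, a filter within 1 group and a split of the controls were added after the data were seen. The software was R 4.3.3 with limma 3.58.1, and Python 3.11.15 with matplotlib 3.10.9 for figures.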

Results

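Total RNA from splenic CD8+ T cells of C57BL/6 mice was profiled on 6 Illumina mouse bead arrays in 3 groups of 2. The cells were pre-treated with DMSO (the vehicle), with 0.5 µM epoxomicin, an inhibitor of the proteasome, or with 1 µM E9, a code-named compound that the labels call an activator of the proteasome. Activation followed, for 3 days, with immobilized antibodies to CD3 and CD28 (5 µg/ml) and IL-2 in the medium. The design text speaks of biological duplicates of CD8+CD44+ cells, and the labels do not say which arrays share an animal or a day. The deposited intensities ran from 22 to 18026.1 with a median of 34.2 on every array, since the authors had made all arrays alike by quantile normalization. The 13524 tested genes correlated between the 2 arrays of a group with r of 0.997 for DMSO, 0.998 for epoxomicin and 0.996 for E9, across genes, which are not independent replicates. The first principal component held 68.9% of the variance and set both E9 arrays apart from the other 4, and the second held 12.6% and set epoxomicin apart from DMSO. Fold changes are on the log2 scale, each with the standard error of the model (SE, 2 arrays per group).

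The first comparison asks what inhibiting the proteasome before activation left in the transcriptome of the activated cells. With epoxomicin, transcripts of some secreted mediators were higher than with DMSO: the chemokine gene Ccl9 rose (log2 fold change 1.14 ± 0.065 (SE), adjusted p = 0.000231), from an intensity of 895 ± 35.4 to 2006 ± 47 (SD, n = 2), and so did the growth factor gene Il3 (log2 fold change 0.82 ± 0.076 (SE), adjusted p = 0.00242). The glucose transporter genes Slc2a3 (log2 fold change -0.67 ± 0.10 (SE), adjusted p = 0.018) and Slc2a1 (log2 fold change -0.46 ± 0.083 (SE), adjusted p = 0.0313) fell. So did Chac1, a stress-induced enzyme that breaks down glutathione (log2 fold change -0.81 ± 0.066 (SE), adjusted p = 0.00162), and Ctla4, an inhibitory receptor of T cells (log2 fold change -0.99 ± 0.099 (SE), adjusted p = 0.00356). The lowest value belonged to Igk-C, the constant region of the immunoglobulin kappa chain made by B cells (log2 fold change -1.69 ± 0.16 (SE), adjusted p = 0.00242), which went from 214 ± 21.1 to 48.6 ± 0.707 (SD, n = 2).

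Of 13524 genes, 170 changed, 96 up and 74 down, and 4 of them by at least 2-fold (Ccl9 up, and Igk-C, Anxa2 and Egln3 down). Other large increases were Afp (0.91), Cd160 (0.76), Ipcef1 (0.70), Tnfsf14 (0.69), Mlkl (0.69) and Anxa3 (0.68), with SE 0.067 to 0.090, adjusted p from 0.00162 to 0.00742. Cd160 encodes a co-signalling receptor of cytotoxic lymphocytes, Tnfsf14 the cytokine LIGHT, Mlkl the executor of necroptosis and Afp alpha-fetoprotein. Other large decreases were Anxa2 (-1.10), Egln3 (-1.002), Tubb2b (-0.86), Cd81 (-0.82) and H2-Ab1 (-0.79), with SE 0.073 to 0.16, adjusted p from 0.0018 to 0.0225. Egln3 encodes a prolyl hydroxylase of hypoxia-inducible factors, Tubb2b a beta-tubulin, Cd81 a tetraspanin and H2-Ab1 an MHC class II chain. H2-Aa, another MHC class II chain, was above background with DMSO and not with epoxomicin, which makes it at least 1.24-fold lower. Of the 42 changed genes that the naming rule took, 17 had further probes, 8 with one that also passed and 0 with one that passed the opposite way. No further probe passed for Tnfsf14, Mlkl, Egln3, Tubb2b or H2-Ab1 here, nor for Trib3, Srxn1, Egr3 or Gbp3 below.

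Of 39 gene lists tested, 6 were higher and 5 lower with epoxomicin. The adjusted p with an estimated correlation, given beside each, rests on 3 residual degrees of freedom and has little power. In the list of ATF4 targets, which serve amino acid supply and the response to stress, 4 of the 21 measured members fell (7 when adjusted over the list alone): Chac1, Trib3 (-0.69), Ddit4 (-0.62) and Phgdh (-0.32). For the ATF4 list the median was -0.13 (camera adjusted p = 2.23e-09, adjusted p = 0.187 with an estimated correlation). In the glycolysis list 3 of the 18 measured members fell (8 when adjusted over the list alone), Slc2a3, Slc2a1 and the phosphofructokinase gene Pfkp (-0.65). For glycolysis the median was -0.23 (camera adjusted p = 4.17e-10, adjusted p = 0.301 with an estimated correlation). Among mitosis genes 1 of the 23 measured members fell (8 when adjusted over the list alone), the spindle factor gene Tpx2 (-0.42). For mitosis the median was -0.17 (camera adjusted p = 2.23e-09, adjusted p = 0.187 with an estimated correlation). In the DNA replication list none of the 25 measured members passed (0 when adjusted over the list alone). For DNA replication the median was -0.076 (camera adjusted p = 0.0173, adjusted p = 0.309 with an estimated correlation).

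In the cytokine and chemokine list 4 of the 20 measured members rose (7 when adjusted over the list alone): Ccl9, Il3, Ccl1 (0.66) and Tnf (0.60). For the cytokine list the median was 0.16 (camera adjusted p = 1.79e-06, adjusted p = 0.187 with an estimated correlation). In the effector list 3 of the 19 measured members rose (8 when adjusted over the list alone, with 2 lower): Tnf, the chemokine gene Ccl3 (0.51) and the protease gene Ctsw (0.44). For the effector list the median was 0.11 (camera adjusted p = 0.000865, adjusted p = 0.187 with an estimated correlation). Among inhibitory receptors and NR4A factors 5 of the 10 measured members rose and 1 fell (5 and 1 when adjusted over the list alone), with Cd160, Nr4a2 (0.55) and the receptor gene Lag3 (0.45) up and Ctla4 down. For these receptors and factors the median was 0.25 (camera adjusted p = 0.000148, adjusted p = 0.196 with an estimated correlation). In the memory or naive list 3 of the 20 measured members rose (5 when adjusted over the list alone): Klf2 (0.64), a transcription factor of lymphocyte circulation, Cd27 (0.44) and the chemokine receptor gene Cxcr3 (0.43). For the memory list the median was 0.10 (camera adjusted p = 0.00401, adjusted p = 0.268 with an estimated correlation). In the T cell identity list 1 of the 12 measured members rose (6 when adjusted over the list alone), the receptor kinase gene Zap70 (0.48). For T cell identity the median was 0.23 (camera adjusted p = 2.05e-07, adjusted p = 0.187 with an estimated correlation).

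Markers of other cell types moved beside these groups. In the B cell list 4 of the 9 measured members fell (4 when adjusted over the list alone): H2-Ab1, H2-Aa, Cd74 (-0.58), the class II invariant chain, and Cd79b (-0.50), a chain of the B cell receptor. For B cell markers the median was -0.067 (camera adjusted p = 2.19e-05, adjusted p = 0.187 with an estimated correlation). In the NK cell list none of the 6 measured members passed (3 when adjusted over the list alone). For NK cell markers the median was 0.22 (camera adjusted p = 0.000589, adjusted p = 0.187 with an estimated correlation). Activated CD8+ T cells also make several of these receptors.

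The other 28 lists were not called, the smallest camera adjusted p being 0.0571, and the median and mean differed in sign in 5 of them and in none of the called. No member passed over all genes in the lists of the 20S proteasome core, the 19S regulator, the immunoproteasome, proteasome assembly and ubiquitin supply, cytosolic heat shock chaperones, the endoplasmic reticulum unfolded protein response, p53 targets, apoptosis regulators, MYC targets, oxidative phosphorylation, tricarboxylic acid cycle, fatty acid oxidation, cholesterol synthesis, amino acid transport, MHC class I presentation, cell cycle inhibitors, ribosomal proteins, aminoacyl-tRNA synthetases, autophagy and lysosome, CD4 and regulatory T cell markers, myeloid and dendritic cell markers, neutrophil markers and erythroid and platelet markers. Adjusted over the list alone, members passed in proteasome assembly and ubiquitin supply (1), apoptosis regulators (1), fatty acid oxidation (2), cholesterol synthesis (1), amino acid transport (2) and autophagy and lysosome (2). Srxn1, which repairs oxidized peroxiredoxins, rose (0.59) as the 1 member of 15 in the NRF2 list (1 adjusted over the list alone), and the desaturase gene Scd2 fell (-0.53) as 1 of 11 for fatty acid synthesis (1 adjusted over the list alone). The guanylate-binding protein genes Gbp2 (-0.64) and Gbp3 (-0.54) fell as 2 of 21 interferon response genes (4 adjusted over the list alone). Egr2 (0.56) and Egr3 (0.55), transcription factors downstream of the antigen receptor, rose as 2 of 17 activation genes (with 5 higher and 4 lower adjusted over the list alone), and Ccl1 was the 1 of 18 NF-kB targets that rose (3 adjusted over the list alone). The gamma delta T cell list had 2 measured members, too few to test, and neither passed in any comparison. Of the genes set to be named whatever their values, Slc2a1 is given above and the following did not pass: Myc (-0.058), Psmb5 (0.20), Psmd4 (-0.0043), Hspa1b (0.0048), Ifng (0.49), Prf1 (-0.33), Il7r (0.22), Tbx21 (-0.21), Eomes (0.32), Klrg1 (0.12), Cd44 (0.040), Il2ra (0.011), Ldha (-0.090) and Cpt1a (0.15), with SE 0.061 to 0.19, adjusted p from 0.13 to 0.995. Klrg1 and Cpt1a were not above background with DMSO, and Hspa1b was not on both arrays of any group, so their values say little in any comparison. Probes for Hmox1, Gzmb and Prdm1 were not above background on 2 arrays, and no probe here carried the name Tcf7 or Hk2, which says nothing about their expression.

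Far fewer of the 170 genes passed when any 1 of the DMSO or epoxomicin arrays was left out. Each such fit left a lone array in a group, assumed to vary like the rest, and had less power. The sign turned for 0 of the 170 genes in these fits, which share their other arrays with the full fit. Ccl9 was 1.12 without epoxomicin 2. With the replicate number as a block 91 passed. The lists called also by fry, which does not compare a list with other genes, numbered 7 of the 11 (not glycolysis, DNA replication, mitosis or memory), and the DNA replication list lost its call without DMSO 1 (camera adjusted p = 0.171) and without epoxomicin 2 (camera adjusted p = 0.121).

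The comparison of E9 with DMSO asks the same of the compound given as a proteasome activator. Transcripts of several cytokines and chemokines that activated CD8+ T cells secrete were much lower with E9: Il2, the T cell growth factor, fell (log2 fold change -3.20 ± 0.072 (SE), adjusted p = 4.8e-08), from 771 ± 31.1 to 61.1 ± 5.52 (SD, n = 2), and with it Ifng, interferon gamma (log2 fold change -2.53 ± 0.12 (SE), adjusted p = 1.76e-06), and the chemokine genes Xcl1 (log2 fold change -3.31 ± 0.11 (SE), adjusted p = 1.63e-07) and Ccl1 (log2 fold change -3.39 ± 0.11 (SE), adjusted p = 1.63e-07). Of the lists described below, 20 of 23 mitosis genes and 10 of 17 of cholesterol synthesis fell (camera adjusted p = 4.48e-14 and adjusted p = 1.62e-06, but adjusted p = 0.123 and adjusted p = 0.123 with an estimated correlation). In the other direction, 12 of 16 genes of MHC class I presentation and 12 of 21 of the interferon response rose (camera adjusted p = 7e-08 and adjusted p = 1.85e-08, but adjusted p = 0.123 and adjusted p = 0.123 with an estimated correlation). Among the largest increases were those of Lmna, which encodes the nuclear lamins A and C (log2 fold change 2.89 ± 0.084 (SE), adjusted p = 1.22e-07), Ly6c1, a surface protein of memory CD8+ T cells (log2 fold change 2.52 ± 0.077 (SE), adjusted p = 1.22e-07), and Vim, the filament protein vimentin (log2 fold change 2.07 ± 0.089 (SE), adjusted p = 8.27e-07).

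In all, 2046 genes changed, 1017 up and 1029 down, and 165 of them by at least 2-fold. Other large increases were in Anxa3 (2.18), Hsd11b1 (1.97), St3gal6 (1.95), Klra13-ps (1.95) and Cox6a2 (1.94), with SE 0.062 to 0.074, adjusted p from 1.49e-07 to 3.36e-07. Hsd11b1 encodes an enzyme that activates glucocorticoids, St3gal6 a sialyltransferase and Cox6a2 a muscle form of a cytochrome c oxidase subunit. Other large decreases were in Tnfrsf4 (-2.40), Cd200 (-2.39), Bdh2 (-2.35) and Ccl9 (-2.33), with SE 0.064 to 0.12, adjusted p from 1.08e-07 to 1.76e-06. Tnfrsf4 encodes the costimulatory receptor OX40 and Cd200 an inhibitory ligand. Some transcripts were above background in 1 group alone, which gives bounds: Il3 was at least 2.73-fold lower with E9, Idi2 at least 2.45-fold, Acsl6 at least 1.49-fold and Ticam2 at least 1.48-fold lower. Fgl2 was at least 1.59-fold higher, Scimp at least 1.54-fold, Gbp11 at least 1.48-fold and Oasl2 at least 1.45-fold higher. Of the 115 changed genes under the naming rule, 58 had further probes, and one of these passed the same way for 44 and the opposite way for 0. Among those named below, no further probe passed for Cdk1 or Pfkl.

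**Figure D1:**
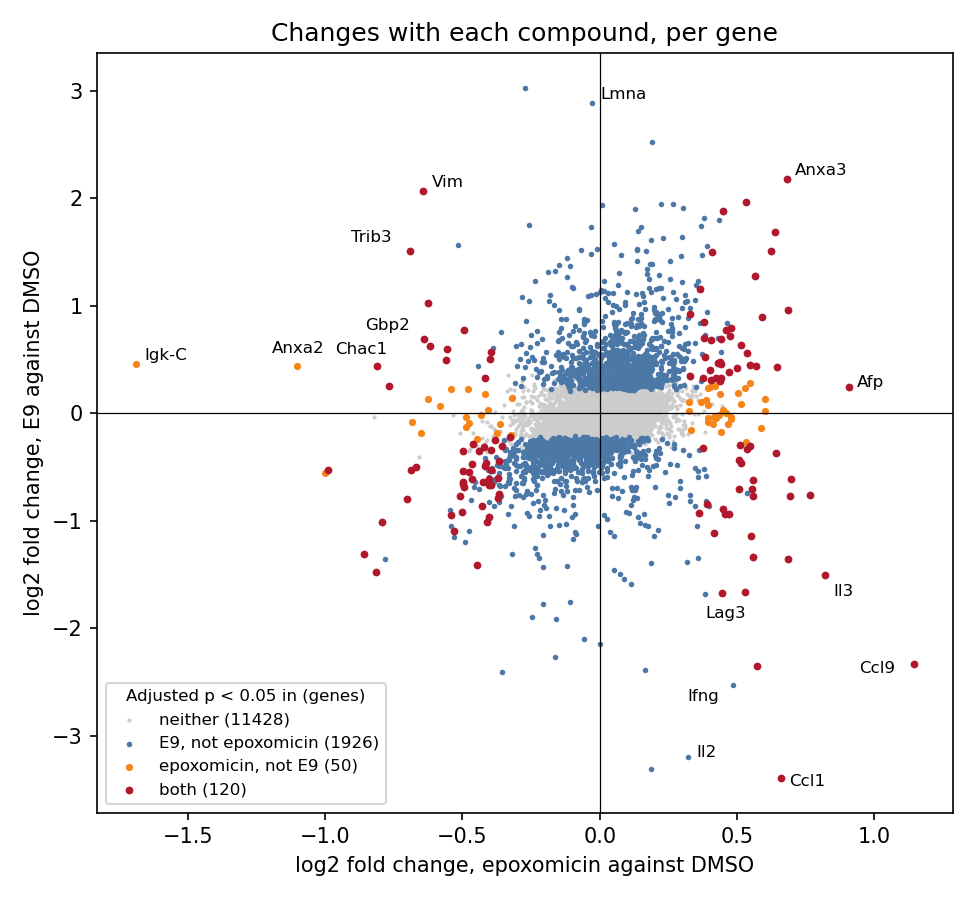
Each point is 1 of 13524 genes, with its log2 fold change with epoxomicin against DMSO on the x axis and with E9 against DMSO on the y axis, coloured by which comparison it passed. Ccl9 sits at 1.14 and -2.33 and Vim at -0.64 and 2.07, 2 genes that changed in opposite directions, while Anxa3 rose with both (0.68 and 2.18).

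Gene lists called with E9 numbered 17, 8 higher and 9 lower. Among mitosis genes 20 of the 23 measured members fell (22 when adjusted over the list alone), for example Cdk1 (-0.70), the kinase that starts mitosis, and Top2a (-0.67). For mitosis the median was -0.49 (camera adjusted p = 4.48e-14, adjusted p = 0.123 with an estimated correlation). In the DNA replication list 1 of the 25 measured members rose and 12 fell (1 and 15 when adjusted over the list alone), with Gins2 (-0.61) and Rrm1 (-0.48) among the lower. For DNA replication the median was -0.30 (camera adjusted p = 1.89e-05, adjusted p = 0.132 with an estimated correlation). In the cholesterol synthesis list 10 of the 17 measured members fell (11 when adjusted over the list alone), with Stard4 (-0.72), Lss (-0.65) and Mvd (-0.53). For cholesterol synthesis the median was -0.34 (camera adjusted p = 1.62e-06, adjusted p = 0.123 with an estimated correlation). In the fatty acid synthesis list 6 of the 11 measured members fell (6 when adjusted over the list alone), with the desaturase genes Scd1 (-1.31) and Scd2 (-1.09). For fatty acid synthesis the median was -0.24 (camera adjusted p = 0.00305, adjusted p = 0.222 with an estimated correlation). In the glycolysis list 5 of the 18 measured members fell (9 when adjusted over the list alone), with Pfkl (-0.54), Slc2a3 (-0.50), Hk1 (-0.41) and Slc2a1 (-0.29). For glycolysis the median was -0.24 (camera adjusted p = 0.00123, adjusted p = 0.479 with an estimated correlation).

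In the list of NF-kB targets 1 of the 18 measured members rose and 10 fell (1 and 12 when adjusted over the list alone), with Cd83 (-2.10) and the inhibitor gene Nfkbia (-1.05) among the lower. For NF-kB targets the median was -0.43 (camera adjusted p = 5.77e-07, adjusted p = 0.123 with an estimated correlation). In the activation and costimulation list 3 of the 17 measured members rose and 8 fell (4 and 11 when adjusted over the list alone), with Il2, Tnfrsf4 and Tnfrsf18 (-0.64) down and the adhesion receptor gene Cd44 up (0.64). For the activation list the median was -0.22 (camera adjusted p = 0.00329, adjusted p = 0.21 with an estimated correlation). Among inhibitory receptors and NR4A factors 1 of the 10 measured members rose and 5 fell (1 and 6 when adjusted over the list alone), with Lag3 (-1.67), Nr4a2 (-1.14), Cd160 (-0.76) and Ctla4 (-0.53) down. For these receptors and factors the median was -0.27 (camera adjusted p = 0.00329, adjusted p = 0.21 with an estimated correlation). In the cytokine and chemokine list 4 of the 20 measured members rose and 6 fell (5 and 7 when adjusted over the list alone); its median was 0.0076 and its mean -0.63, of opposite sign, and it was not called (camera adjusted p = 0.099). In the effector list 5 of the 19 measured members rose and 4 fell (6 and 5 when adjusted over the list alone), with Ifng and the transcription factor gene Zeb2 (-1.39) down and Il12rb2 (1.08) and the chemokine gene Ccl5 (0.84) up; its median was 0.019, its mean -0.12, and it was not called (camera adjusted p = 0.932). In the cytosolic heat shock list 6 of the 19 measured members fell (6 when adjusted over the list alone), with Stip1 (-0.48) and Hsph1 (-0.45). For these chaperones the median was -0.18 (camera adjusted p = 0.00123, adjusted p = 0.21 with an estimated correlation).

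In the memory or naive list 13 of the 20 measured members rose and 4 fell (14 and 4 when adjusted over the list alone); Ly6c1, Klf2 (1.69), the chromatin organizer gene Satb1 (1.30) and the IL-7 receptor gene Il7r (1.29) rose. For the memory list the median was 0.38 (camera adjusted p = 1.93e-05, adjusted p = 0.132 with an estimated correlation). In the T cell identity list 8 of the 12 measured members rose (8 when adjusted over the list alone), with Cd2 (1.63) and the receptor chain gene Cd3g (0.80). For T cell identity the median was 0.51 (camera adjusted p = 3e-07, adjusted p = 0.123 with an estimated correlation). In the NK cell list 3 of the 6 measured members rose (3 when adjusted over the list alone): Klrd1 (1.75), Klra3 (1.19) and Klre1 (0.98), lectin-like receptors of NK cells that CD8+ T cells can also express. For NK cell markers the median was 0.52 (camera adjusted p = 0.00103, adjusted p = 0.132 with an estimated correlation). In the list for presentation on MHC class I 12 of the 16 measured members rose (13 when adjusted over the list alone), with H2-M3 (0.64) and the transactivator gene Nlrc5 (0.52). For MHC class I the median was 0.30 (camera adjusted p = 7e-08, adjusted p = 0.123 with an estimated correlation). In the immunoproteasome list 4 of the 6 measured members rose (4 when adjusted over the list alone): Psmb10 (1.01), Psmb8 (0.38), Psmb9 (0.32) and Psme1 (0.34). For the immunoproteasome the median was 0.33 (camera adjusted p = 0.00183, adjusted p = 0.141 with an estimated correlation). In the interferon response list 12 of the 21 measured members rose (13 when adjusted over the list alone), with Ifit3 (1.34), Usp18 (1.05) and Gbp2 (0.69). For the interferon list the median was 0.32 (camera adjusted p = 1.85e-08, adjusted p = 0.123 with an estimated correlation). In the ATF4 list 8 of the 21 measured members rose (12 when adjusted over the list alone, with 1 lower), with Trib3 (1.51) and Ddit3 (1.38), the transcription factor CHOP. For the ATF4 list the median was 0.23 (camera adjusted p = 8.94e-07, adjusted p = 0.132 with an estimated correlation). In the list of the endoplasmic reticulum unfolded protein response 8 of the 19 measured members rose (10 when adjusted over the list alone), with the transcription factor gene Xbp1 (1.11) and Dnajc3 (0.51). For the endoplasmic reticulum the median was 0.27 (camera adjusted p = 4.58e-06, adjusted p = 0.21 with an estimated correlation).

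The 22 lists not called had camera adjusted p of 0.0597 or more. Median and mean differed in sign in 5 of them, the cytokine and effector lists included, and in none of the called. No member passed, over all genes or adjusted over the list alone, in the lists of the 20S proteasome core, the 19S regulator, oxidative phosphorylation and ribosomal proteins. The counts were 1 up and 0 down of 16 for proteasome assembly and ubiquitin supply, 1 up and 2 down of 15 for NRF2 targets and metallothioneins, 2 up and 2 down of 18 for p53 targets, 3 up and 2 down of 15 for apoptosis regulators and 0 up and 2 down of 23 for MYC targets. They were 1 up and 0 down of 13 for tricarboxylic acid cycle, 2 up and 4 down of 17 for fatty acid oxidation, 1 up and 0 down of 9 for amino acid transport, 1 up and 1 down of 10 for cell cycle inhibitors, 1 up and 1 down of 19 for aminoacyl-tRNA synthetases and 2 up and 1 down of 18 for autophagy and lysosome. Among them were the metallothionein gene Mt1 (-1.10), the survival genes Bcl2 (1.13) and Bcl2l1 (-0.99) and the autophagy receptor gene Sqstm1 (0.61). Markers of other cell types gave 0 up and 2 down of 7 for CD4 and regulatory T cell markers, 0 up and 2 down of 9 for B cell markers, 1 up and 0 down of 9 for myeloid and dendritic cell markers, 1 up and 0 down of 6 for neutrophil markers and 1 up and 0 down of 7 for erythroid and platelet markers. H2-Ab1 (-1.01) and Cd79b (-0.65) were the B cell genes that fell, Ctss (0.91) the myeloid gene that rose, and Igk-C did not pass (0.46, adjusted p = 0.0862). Adjusted over the list alone these counts were the same, but for 4 apoptosis regulators up and 3 genes of fatty acid oxidation up. Of the genes named whatever their values, Tbx21, the effector transcription factor T-bet, fell (-0.54) and its relative Eomes rose (0.89). Those that did not pass were Myc (-0.21), Psmb5 (-0.11), Psmd4 (0.16), Hspa1b (-0.048), Prf1 (-0.60), Klrg1 (0.17), Il2ra (-0.16), Ldha (-0.043) and Cpt1a (0.067), with SE 0.061 to 0.19, adjusted p from 0.0542 to 0.771.

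Without DMSO 1, 1311 genes passed, and without DMSO 2, 1228. All 17 called lists but glycolysis were called by fry too. None passed with an estimated correlation, where the unadjusted p was under 0.05 for 11 lists. On 3 residual degrees of freedom that failure does not show whether correlation gave the calls.

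**Figure D2:**
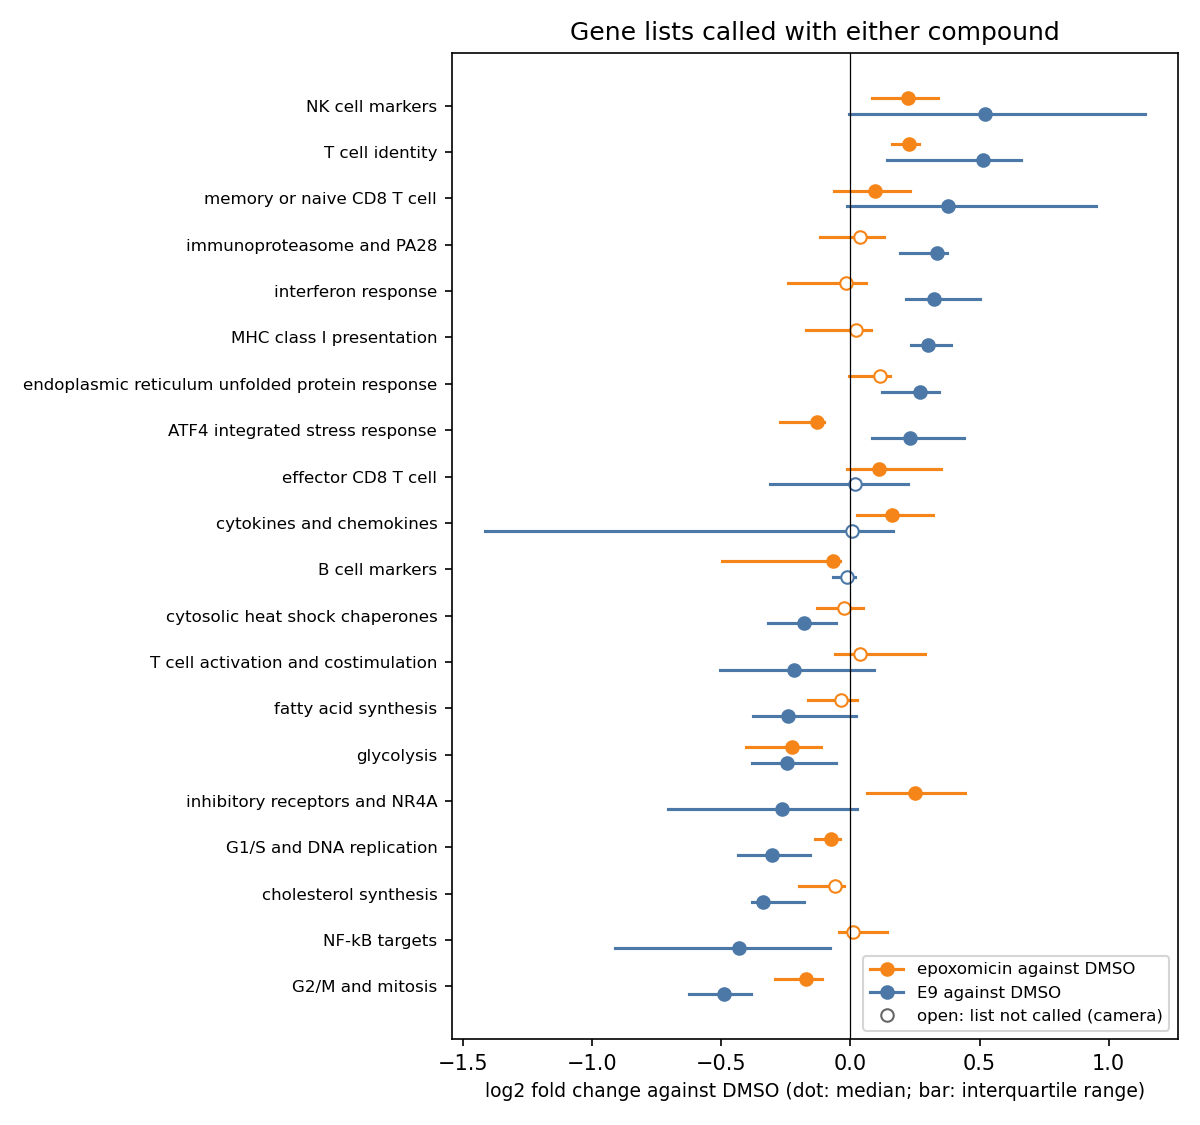
Each dot is the median log2 fold change of a gene list's measured members against DMSO and each bar their interquartile range, for epoxomicin (orange) and E9 (blue), with open dots for lists not called by camera. The ATF4 list lies at -0.13 with epoxomicin and 0.23 with E9, and the mitosis list at -0.17 and -0.49.

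The direct comparison asks where the cells given the inhibitor differed from those given the activator, at doses that were not matched (0.5 µM epoxomicin, 1 µM E9). In the cytokine list 9 of 20 members were higher with epoxomicin than with E9 and 4 lower (camera adjusted p = 0.00124, but adjusted p = 0.143 with an estimated correlation). Transcripts of single mediators that were higher included Ccl1 (log2 fold change 4.05 ± 0.11 (SE), adjusted p = 7.21e-08), Il2 (log2 fold change 3.52 ± 0.072 (SE), adjusted p = 9.89e-09), Ccl9 (log2 fold change 3.48 ± 0.065 (SE), adjusted p = 8.03e-09) and Ifng (log2 fold change 3.01 ± 0.12 (SE), adjusted p = 4.92e-07). Lower with epoxomicin were Lmna (log2 fold change -2.91 ± 0.084 (SE), adjusted p = 8.4e-08), Vim (log2 fold change -2.71 ± 0.089 (SE), adjusted p = 1.58e-07) and Ly6c1 (log2 fold change -2.33 ± 0.077 (SE), adjusted p = 1.59e-07). Of the 21 ATF4 targets of the integrated stress response 13 were lower (camera adjusted p = 6.24e-14, but adjusted p = 0.129 with an estimated correlation), among them Trib3, a pseudokinase induced by ATF4 (log2 fold change -2.20 ± 0.092 (SE), adjusted p = 4.92e-07).

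In all, 1706 genes differed, 811 higher and 895 lower with epoxomicin, and 164 by at least 2-fold. Further large differences were Xcl1 (3.50), Bdh2 (2.92), Cd200 (2.55) and Slamf1 (2.19), with SE 0.064 to 0.11, adjusted p from 1.25e-08 to 2.73e-07, and on the lower side Igk-C (-2.14), Tgm2 (-2.08), Gimap7 (-2.01) and Cox6a2 (-1.93), with SE 0.069 to 0.16, adjusted p from 1.95e-07 to 1.73e-05. Slamf1 encodes a receptor between lymphocytes, Tgm2 a transglutaminase and Gimap7 a lymphocyte GTPase. Transcripts above background with epoxomicin and not with E9 were Il3, at least 4.82-fold higher, Idi2, at least 3.14-fold, Acsl6, at least 2.18-fold, and Adh4, at least 1.78-fold higher. The reverse held for Car2, at least 1.95-fold lower with epoxomicin, Fgl2, at least 1.59-fold, Scimp, at least 1.54-fold, and Gbp11, at least 1.48-fold lower. Of the 109 named genes that differed, 51 had further probes, 35 with one passing the same way and 0 the opposite way, and none passed for Tgm2, Egr3 or Mki67.

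Of the lists, 10 were higher and 10 lower with epoxomicin than with E9. The ATF4 list was lower, with 13 lower of 21 (16 adjusted over the list alone), among them Ddit3 (-1.53), Chac1 (-1.25) and Ddit4 (-1.24). For the ATF4 list the median was -0.38 (camera adjusted p = 6.24e-14, adjusted p = 0.129 with an estimated correlation). The interferon list had 15 lower of 21 (16 adjusted over the list alone, and 1 higher), with Gbp2 (-1.33) and Usp18 (-1.30). For the interferon list the median was -0.40 (camera adjusted p = 1.38e-11, adjusted p = 0.129 with an estimated correlation). The MHC class I list had 10 lower of 16 (12 adjusted over the list alone), with Tapbpl (-0.61). For MHC class I the median was -0.33 (camera adjusted p = 1.11e-08, adjusted p = 0.129 with an estimated correlation). The immunoproteasome list had 3 lower of 6 (3 adjusted over the list alone), with Psmb10 (-0.96). For the immunoproteasome the median was -0.35 (camera adjusted p = 0.00251, adjusted p = 0.143 with an estimated correlation). The endoplasmic reticulum list had 3 lower of 19 (5 adjusted over the list alone), with Xbp1 (-1.13). For the endoplasmic reticulum the median was -0.15 (camera adjusted p = 0.000688, adjusted p = 0.217 with an estimated correlation). The amino acid transport list had 1 lower of 9 (3 adjusted over the list alone), the glycine transporter gene Slc6a9 (-0.80). For amino acid transport the median was -0.075 (camera adjusted p = 0.0282, adjusted p = 0.197 with an estimated correlation). The memory or naive list was lower, with 3 higher and 10 lower of 20 (4 and 11 adjusted over the list alone), Satb1 (-1.13) and Il7r (-1.07) among the lower. For the memory list the median was -0.26 (camera adjusted p = 0.00046, adjusted p = 0.143 with an estimated correlation). The T cell identity list was lower too, with 1 higher and 6 lower of 12 (1 and 7 adjusted over the list alone), Cd2 (-1.40) lower and Zap70 (0.51) higher. For T cell identity the median was -0.27 (camera adjusted p = 0.000861, adjusted p = 0.143 with an estimated correlation).

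Among the higher lists, the NF-kB targets had 11 higher and 1 lower of 18 (12 and 1 adjusted over the list alone), with Cd83 (2.05) and Rel (1.09) higher. For NF-kB targets the median was 0.49 (camera adjusted p = 8.58e-08, adjusted p = 0.129 with an estimated correlation). The mitosis list had 11 higher of 23 (16 adjusted over the list alone), such as Mki67 (0.44). For mitosis the median was 0.28 (camera adjusted p = 1.29e-08, adjusted p = 0.143 with an estimated correlation). The cytokine list had 9 higher and 4 lower of 20 (9 and 5 adjusted over the list alone). For the cytokine list the median was 0.16 (camera adjusted p = 0.00124, adjusted p = 0.143 with an estimated correlation). The list of inhibitory receptors had 6 higher and 2 lower of 10 (7 and 2 adjusted over the list alone), with Lag3 (2.12), Nr4a2 (1.69) and Cd160 (1.53) higher. For these receptors and factors the median was 0.28 (camera adjusted p = 0.000288, adjusted p = 0.143 with an estimated correlation). The activation list had 7 higher and 2 lower of 17 (7 and 3 adjusted over the list alone), with Tnfrsf4 (2.05), Egr2 (1.18) and Egr3 (0.85) higher and Cd44 (-0.60) lower. For the activation list the median was 0.17 (camera adjusted p = 0.00195, adjusted p = 0.174 with an estimated correlation). Cholesterol synthesis had 8 higher of 17 (12 adjusted over the list alone), with Stard4 (0.46). For cholesterol synthesis the median was 0.29 (camera adjusted p = 3.91e-05, adjusted p = 0.129 with an estimated correlation). Fatty acid synthesis had 3 higher of 11 (5 adjusted over the list alone), with Scd1 (1.08). For fatty acid synthesis the median was 0.18 (camera adjusted p = 0.00481, adjusted p = 0.197 with an estimated correlation). DNA replication had 4 higher and 1 lower of 25 (7 and 1 adjusted over the list alone), with Mcm10 (0.44) higher. For DNA replication the median was 0.22 (camera adjusted p = 0.00124, adjusted p = 0.158 with an estimated correlation). The MYC targets had 2 higher of 23 (6 adjusted over the list alone), Ncl (0.39) and Pes1 (0.27), which act in ribosome assembly. For MYC targets the median was 0.15 (camera adjusted p = 0.00124, adjusted p = 0.143 with an estimated correlation). The heat shock list had 3 higher of 19 (3 adjusted over the list alone), with Bag3 (0.65). For these chaperones the median was 0.11 (camera adjusted p = 0.00512, adjusted p = 0.197 with an estimated correlation). Beside these, markers of NK cells were lower, with 3 lower of 6 (3 adjusted over the list alone, and 1 higher). For NK cell markers the median was -0.34 (camera adjusted p = 0.0069, adjusted p = 0.158 with an estimated correlation). Markers of myeloid and dendritic cells were lower too, with 2 lower of 9 (2 adjusted over the list alone), Ctss (-0.89) and Mpeg1, which was not above background with epoxomicin and at least 1.15-fold lower. For the myeloid list the median was -0.12 (camera adjusted p = 0.00742, adjusted p = 0.174 with an estimated correlation).

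The other 19 lists were not called, with camera adjusted p of 0.0522 or more, and none of the members of the 19S regulator or oxidative phosphorylation lists passed, over all genes or adjusted over the list alone. Within the 20S core list Psmb5, a catalytic subunit that epoxomicin binds, was higher with epoxomicin than with E9 (log2 fold change 0.32 ± 0.064 (SE), adjusted p = 0.0108). Median and mean differed in sign in 4 of the lists not called and in none of the called. The counts were 1 higher and 0 lower of 11 for the 20S proteasome core, 1 higher and 1 lower of 16 for proteasome assembly and ubiquitin supply, 3 higher and 1 lower of 15 for NRF2 targets and metallothioneins, 3 higher and 1 lower of 18 for p53 targets, 3 higher and 3 lower of 15 for apoptosis regulators and 0 higher and 1 lower of 18 for glycolysis. They were 0 higher and 1 lower of 13 for tricarboxylic acid cycle, 4 higher and 3 lower of 17 for fatty acid oxidation, 5 higher and 3 lower of 19 for effector CD8 T cell, 0 higher and 1 lower of 10 for cell cycle inhibitors, 0 higher and 1 lower of 20 for ribosomal proteins, 1 higher and 2 lower of 19 for aminoacyl-tRNA synthetases and 0 higher and 2 lower of 18 for autophagy and lysosome. Markers of other cells gave 2 higher and 0 lower of 7 for CD4 and regulatory T cell markers, 0 higher and 2 lower of 9 for B cell markers, 0 higher and 1 lower of 6 for neutrophil markers and 0 higher and 1 lower of 7 for erythroid and platelet markers, with the B cell genes Cd74 (-0.65) and H2-Aa lower, the latter by at least 1.23-fold. Adjusted over the list alone the counts were the same but for 5 genes of fatty acid oxidation higher, 7 effector genes higher, 3 autophagy genes lower and 0 ribosomal protein genes. Of the genes named whatever their values, Eomes was lower (-0.57), and those that did not pass were Myc (0.15), Psmd4 (-0.16), Hspa1b (0.053), Prf1 (0.27), Tbx21 (0.34), Klrg1 (-0.054), Il2ra (0.17), Slc2a1 (-0.17), Ldha (-0.047) and Cpt1a (0.081), with SE 0.061 to 0.19, adjusted p from 0.0626 to 0.773.

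Without epoxomicin 1, 941 genes passed, and without epoxomicin 2, 938; leaving out epoxomicin 1 also ended the calls of the amino acid transport list (camera adjusted p = 0.126) and the myeloid list (camera adjusted p = 0.053), and the myeloid list was also not called without the filter on dim probes (camera adjusted p = 0.0678). All 20 called lists were called by fry too.

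**Figure D3:**
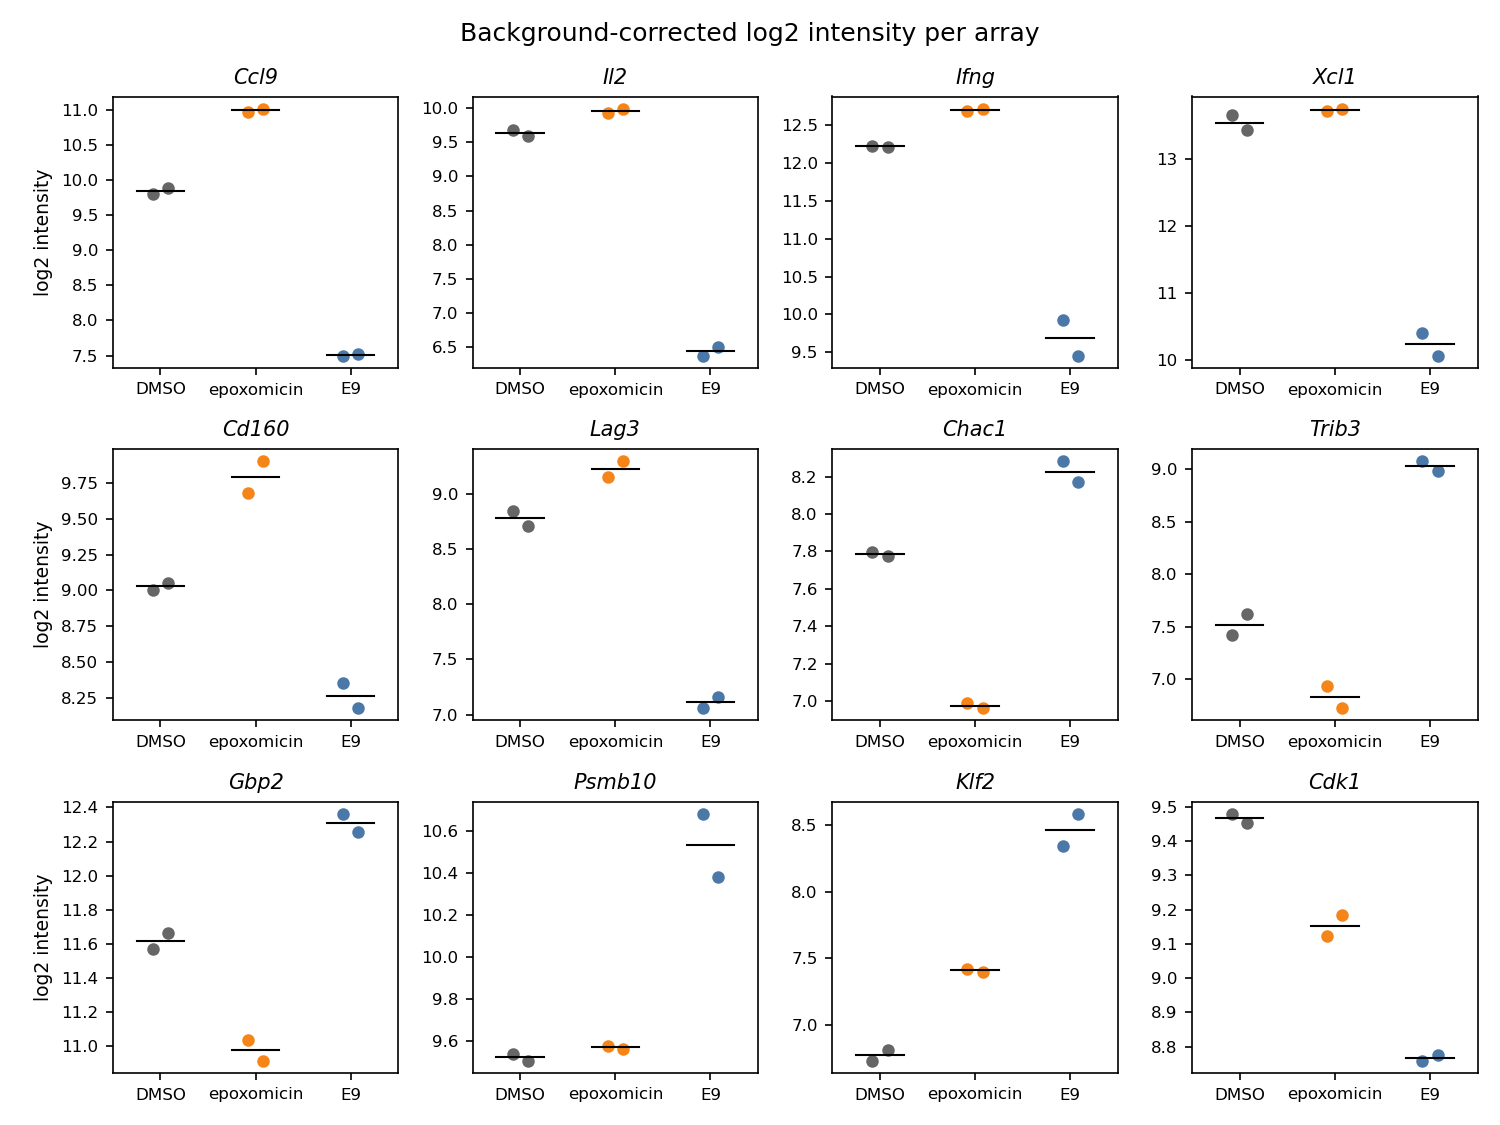
Background-corrected log2 intensity of 12 genes on each of the 6 arrays, with a point per array and a bar at the mean of the 2 arrays of a group; each panel has its own range on the y axis. For Trib3 both epoxomicin arrays lie below and both E9 arrays above the DMSO arrays, and for Ccl9 the order is the reverse.

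Both comparisons with DMSO use the same control arrays. The 120 genes that passed in both were split into 37 higher in both, 41 lower in both, 29 higher with epoxomicin and lower with E9 and 13 lower with epoxomicin and higher with E9. Lists of these sizes drawn independently would share 7.22, 5.63, 7.30 and 5.56, and simulations of unchanged groups gave means of 0.03, 0.02, 0 and 0. Those simulations held no changed gene, so few shared calls could arise in them. They do not show how many shared calls the common controls give when many genes pass. Genes higher with both compounds included Anxa3, Mlkl (0.69 and 0.97) and Klf2, and genes lower with both included Cd81 (-0.82 and -1.47), Tubb2b (-0.86 and -1.31), Ctla4, Scd2 and Slc2a3. The 42 genes that went opposite ways, such as Lag3, Ccl9, Trib3 and Vim, all passed the direct comparison too. This follows from their choice, since the direct change adds both opposite changes at the same SE, so it is no further test. Across genes, which are not independent replicates, the fold changes correlated with r of 0.281, below the 0.501 (range 0.484 to 0.514) that 100 simulations of unchanged groups sharing their controls gave. The simulated groups held no real changes, so these values of r are not directly comparable. Their covariance was 0.0092 against 0.00313 in the simulations, a difference of 0.00608. With a separate DMSO array for each comparison, a split chosen after the data were seen, r was 0.156 and 0.149 and the covariance 0.00571 and 0.00565 in the 2 assignments. The calls were not repeated on such single controls, so part of the shared calls can come from deviations of the controls themselves.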

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

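The tests on shares of the DMSO level and the use of single DMSO arrays for the ATF4 list were chosen after the patterns had been seen, while the list tests and the fits without an array were planned. Of 9 B cell markers 4 were lower with epoxomicin than with DMSO (camera adjusted p = 2.19e-05, but adjusted p = 0.187 with an estimated correlation), as was Igk-C (-1.69), although isolation of CD8+ T cells should remove B cells. If the cultures held fewer B cells, all B cell transcripts would keep a like share of their DMSO level above background; the bright markers kept 0.333 (Cd74), 0.359 (H2-Ab1) and 0.518 (Cd79b), with a median of 0.359, and Igk-C kept 0.0975. The share of Igk-C (0.0948 to 0.100 over its arrays) lay below that of each bright marker (0.278 or more), which is not the like share expected of fewer B cells. The markers nearer the limit kept -0.0498 (H2-Aa), 0.578 (Ms4a1), 0.796 (H2-Eb1) and 0.887 (Fcmr), too dim to decide. Fewer B cells thus stay possible for the markers of the list (Ms4a1, H2-Eb1, Fcmr and Siglech were named outside the rule, after their values were seen). With E9, H2-Ab1 (56.3 against 140.1 with DMSO) and Cd79b (64.9 against 116.4) were lower too. Cd74 (92.35 against 87) and H2-Aa (48.7 against 49.3) stayed near DMSO there. The decreases of H2-Ab1 and Cd79b may thus also come from the shared DMSO arrays, which was not tested. A lower share of all cells other than T cells would lower myeloid markers alike, but only 2 were bright enough to read, Ctss (1.01) and Siglech (1.01), with a median of 1.01, which is too few to exclude it.

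Some cytokine transcripts were lower with E9, 6 of 20 in the list against 4 higher: Ccl1, Ccl9, Il2, Il3, Xcl1 and Tnfsf11 fell (the last named outside the rule, after its value was seen). A larger share of unstimulated cells in the E9 cultures would leave a like share of all transcripts of stimulated cells, but the median share left was 0.593 for 23 mitosis genes and 0.0691 for the 6 cytokine genes, a ratio of 8.58, which argues against it as the whole cause. The part played by the authors' quantile normalization was not tested, since no values from before it were used here. A shifted peak of expression stays open too, since cells were taken at a single time.

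The ATF4 list was lower with epoxomicin and higher with E9, with a direct median of -0.38. It was picked for passing all 3 comparisons, so the direct one is no further test of it, and with an estimated correlation it passed none of them (adjusted p = 0.187 with epoxomicin, adjusted p = 0.132 with E9 and adjusted p = 0.129 directly). Against either DMSO array alone both calls held (largest camera adjusted p = 1.33e-05), which argues against a deviation of 1 of them as the whole cause. A deviation common to both DMSO arrays was not tested as a source of the opposite signs against DMSO and stays open for them. It cannot give the direct difference of epoxomicin and E9, which uses no DMSO array. The authors' normalization was not tested either and stays open beside a difference between inhibitor and activator, whose doses differed.

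The effects of the compounds differed in sign elsewhere too, counted where each comparison with DMSO and the direct comparison passed. As for the ATF4 list, the direct comparison is no further test of what was picked in this way. The list of inhibitory receptors and NR4A factors was higher with epoxomicin and lower with E9, with a direct median of 0.28, but passed no comparison with an estimated correlation (adjusted p = 0.196, adjusted p = 0.21 and adjusted p = 0.143). In all, 42 genes changed in opposite directions. Among the named genes, the direct log2 fold changes of epoxomicin against E9 were above 0 for Acsl6 (1.26), Bdh2 (2.92), Ccl1 (4.05), Ccl3 (0.97), Ccl9 (3.48), Cd160 (1.53), Egr2 (1.18), Egr3 (0.85), Il3 (2.32), Ipcef1 (1.31), Lag3 (2.12), Nr4a2 (1.69), Slamf1 (2.19) and Tnfsf14 (2.05). They were below 0 for Chac1 (-1.25), Ddit4 (-1.24), Gbp2 (-1.33), Trib3 (-2.20) and Vim (-2.71). Il3 and Acsl6 were not above background with E9, so their values here are not the bounds given before. Among 4177 probes without a gene name, which no comparison used, 7 changed with epoxomicin, 353 with E9 and 278 between epoxomicin and E9.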

How the results depend on the processing

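The offset of 16, the filter within 1 group and the split of the controls were chosen after the data were seen; the other alternatives were planned. Over that offset, that filter and the choices of background correction, filter on dim probes, probe, variance model and groups in the fit, the number of changed genes stayed within 124 to 238 for epoxomicin against DMSO, 1755 to 2051 for E9 against DMSO and 1462 to 1679 for epoxomicin against E9. Of the 196 calls of named genes, 1 to 17 were lost per alternative, most with the offset of 16, and none reversed. Among all called genes, the mean of a gene's probes turned the sign of 1 with E9 and 3 in the direct comparison. A threshold of at least 2-fold left 4, 165 and 164 genes, by its construction.

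With the replicate number as a block, 91 genes passed for epoxomicin against DMSO, 90 of them among the 170, 1760 for E9 against DMSO and 1413 for epoxomicin against E9, and 12, 17 and 21 lists were called. The deviations of equally numbered arrays correlated across genes with 0.21 (DMSO and epoxomicin), -0.32 (DMSO and E9) and -0.20 (epoxomicin and E9). The numbers as given thus do not show a pairing, and the block costs residual degrees of freedom. Exchanging the numbers of the E9 arrays would make each of these correlations positive. A pairing under other numbers is therefore not excluded, and it was not fitted. Leaving out 1 array at a time, the counts ran from 1 to 238, from 1228 to 1878 and from 938 to 1608, with fewer arrays in each fit, and the correlation of the changes from 0.244 to 0.354. With a separate DMSO array for each comparison that correlation moved to 0.156 and 0.149. With an estimated correlation, 0, 0 and 0 lists were called by camera (unadjusted p under 0.05 for 8, 11 and 12). That test rests on few residual degrees of freedom and has little power. With fry, which tests another question, 7, 26 and 27 were called. The DNA replication list with epoxomicin was not called with the offset of 16 (camera adjusted p = 0.0593).

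Leaving out an array lost 6 to 53 of the 196 calls of named genes and reversed none. The named genes that did reverse passed neither in the reported analysis nor in the setting that reversed them. For epoxomicin against DMSO, Hspa1b was -0.050 without the filter. Leaving out single arrays gave -0.035 to 0.045 for Hspa1b, -0.11 to 0.10 for Psmd4, -0.081 to 0.16 for Cd44 and -0.11 to 0.13 for Il2ra. For E9 against DMSO it gave -0.35 to 0.025 for Il2ra and -0.092 to 0.0069 for Ldha, and for epoxomicin against E9 -0.014 to 0.36 and -0.10 to 0.0022. The cause was not tested. Planned median scaling of raw intensities, the neqc correction and a block for slide or date were not run. No raw column carried a sample label, matching these columns by their values was not tried, and no date was given. The authors' table, planned as an alternative, became the source. Signal over background limits dim genes, whose changes are understated.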

Other observations

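Gene families were grouped by the letters of their symbols after the data had been seen, 285 in all, and some of their members also stand in the lists. With E9, 7 were called, with epoxomicin 6 and between epoxomicin and E9 10. None passed with an estimated correlation (adjusted p = 0.976, adjusted p = 0.981 and adjusted p = 0.93 at the smallest). Adjusted over 285 families, that test on 3 residual degrees of freedom has little power. It does not tell correlation between members from too few arrays. In the Klra family, the Ly49 receptors of NK cells and some CD8+ T cells, 8 of 9 rose (median 1.16, camera adjusted p = 2.7e-09) with E9, among them Klra13-ps; the probes of this family are close in sequence, so single members are uncertain. In the Gimap family of lymphocyte GTPases 5 of 7 rose (median 0.58, camera adjusted p = 0.00372) with E9, Gimap7 among them. In the Lgals family of galectins 4 of 7 rose (median 0.48, camera adjusted p = 0.00677) and in the interferon-inducible Ifi family 6 of 9 rose (median 0.44, camera adjusted p = 0.00228). In the Kif family of kinesin motors 7 of 26 fell (median -0.14, camera adjusted p = 0.00953) and in the Tnfsf family of TNF-like ligands 3 of 7 fell (median -0.32, camera adjusted p = 0.00725) with E9. The Klra family was called higher and the Kif family lower with epoxomicin too, with medians of 0.22 and -0.080 (camera adjusted p = 0.00687 and adjusted p = 0.028) but no member that passed. With epoxomicin, in the Gbp family of interferon-induced GTPases 3 of 6 fell (median -0.32, camera adjusted p = 0.00182); with E9 4 rose and 1 fell, not called (camera adjusted p = 0.0564), and directly 5 of 6 were lower (median -0.68, camera adjusted p = 0.000748). In the Ccl family of chemokines 3 of 9 rose (median 0.052, camera adjusted p = 0.00182) with epoxomicin. The Tubb and Cdca families were the other 2 called, both lower (median -0.20 and -0.27, camera adjusted p = 0.0243 and adjusted p = 0.028), as was Cdca with E9 (median -0.47, camera adjusted p = 0.0436). The 10 called between the compounds had medians below 0 for epoxomicin against E9 in Klra, Ifi, Lgals, Gbp, Anxa, Gimap and Pdlim and above 0 in Tnfsf, Ccl and Cdc (camera adjusted p from 8.38e-09 to 0.0491).

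The decreases of Egln3 and of glucose transporters with epoxomicin prompted a hypothesis: that targets of the hypoxia-inducible factors were lower. A list of 25 such targets, without Egln3 and without the glycolysis genes, was written before its values were seen but after the strongest changes had been read, 23 of them measured. Its median was -0.18, 22 of 23 members were below 0 and 3 fell. The camera p-value was 6.24e-11, the outcome the hypothesis predicted, but it was 0.0893 with an estimated correlation. The arrays were the same ones that prompted the hypothesis, so this is no independent test of it. The list was also lower with E9, where 6 members fell and 1 rose (median -0.18, p-value 2.44e-05, and 0.208 with an estimated correlation), and as a whole it did not separate epoxomicin from E9 (p-value 0.75). The member that rose with E9, Cited2 (0.33, adjusted p = 0.0147), was among the 3 that fell with epoxomicin (-0.42, adjusted p = 0.0313) and was the 1 that differed directly (-0.75, adjusted p = 0.00013); it was named outside the rule, after its values were seen. A direct link to proteasome inhibition was not tested, and any change shared by both comparisons may also come from the DMSO arrays.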
